A study of Mus musculus with 6 samples.

How the data were processed

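Libraries of poly-A selected messenger RNA were made from peritoneal macrophages of ID8 tumour-bearing mice, per the labels' protocols. Peritoneal lavage cells were left to adhere to plastic in culture medium, non-adherent cells were washed away and adherent cells were scraped off; flow cytometry for CD45 and F4/80 served as a check of the macrophage population. There were 3 libraries on control diet and 3 on high fat diet, each 1 week after chemotherapy, and each library was placed in its group by its label. The table's columns carry the library names of the labels. The labels do not say whether the RNA was stranded when counted.

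The authors deposited a table of estimated counts per gene, which holds whole numbers; per the submitters' processing notes Salmon 1.10.2, which estimates transcript abundance without full alignment, and DESeq2 1.44.0 were used with the mm10 build. How transcripts were summed to genes and the annotation release are not given in the sources used here. The authors also deposited a table of their own comparison with a log2 fold change and a p-value for each listed gene, per the file headers; that table holds no adjusted p, and its values stop at a 1.2-fold change and a p of 0.00995. Salmon divides reads that fit several transcripts or gene copies by a model, so values of near-identical genes are uncertain, and a gene can be given no counts when a copy takes its reads. Poly-A selection leaves out most non-polyadenylated RNA.

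The count table has 14108 genes, and the smallest total over the 6 libraries is 6 counts, so genes with fewer are not in it. Total counts were 28109108 to 31761487 per library, with a mean 8.90% larger on high fat diet. A count of 0 allows up to 3 counts, or 0.0945 to 0.107 CPM of the unadjusted totals of these libraries; intervals and floors cover counting error only. Of the gene identifiers 14057 were found in GENCODE release 21 for mouse, which is built on the same genome as mm10 and gave coordinates, transcript number, length and GC content, and 51 were not. The symbol differs between table and release for 605 genes, mostly older symbols; Adgre1 stands in the table as Emr1 and Acod1 as Irg1. There was 1 row with no symbol, kept under its identifier. Uniqueness of a gene was taken as the percentage of its 31-base words that occur in no other gene's transcripts.

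Differential expression was tested with edgeR 4.0.16 (quasi-likelihood fit and F test, trimmed mean of M values scaling, filterByExpr by diet) in R 4.3.3 on the counts as deposited, which needed no rounding. The filter removed 2438 genes and kept 99.97% of counts, leaving 11670 tested. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. The SE of a log2 change is its size over the square root of the F statistic. Gene lists were tested with camera (limma 3.58.1) on log CPM with a prior count of 2 and a preset correlation of 0.01, two-sided and adjusted over the 31 lists with at least 5 tested genes. The 38 lists, 24 on macrophage biology, 3 on RNA quality and 11 on other cell types, were fixed before the data were examined, as were the test, the named genes and most of the alternatives. Counts of called list members are over all genes tested; adjusted over the list alone they were the same in 32 lists, and the other 6 are given in the text.

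Named genes were chosen by a rule. It takes the 12 largest rises and the 12 largest falls among called genes with a mean count of at least 50 and no overlap between diets, leaving out predicted or clone-named genes, mitochondrial genes and genes with no symbol. It adds up to 4 members of each list with the smallest p, and any called member where 4 or fewer were called, and a fixed set of 16 genes (Cd36, Fabp4, Plin2, Trem2, Apoe, Arg1, Mrc1, Gata6, Timd4, Ccr2, Il1b, Nos2, Cd274, Adgre1, Ptprc and H2-Aa). Of the resulting genes, 159 were tested and 151 were called. Genes named outside the rule were chosen after their values were seen, and some genes the rule picked are not reported here.

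Before samples were averaged, pairs of libraries were compared by a chi-square test of their counts. The statistic per degree of freedom was 5.43 to 8.24 within control diet and 7.25 to 21.7 within high fat diet. No pair was therefore the same set of counts deposited more than once. The test allows for counting error only, and Salmon's division of reads can add spread, so a library sequenced more than once is not excluded. The edgeR step was tested on simulated counts with the means and library sizes of this comparison (11555 genes in the step). It recovered 35.4% of genes changed by 0.3 on the log2 scale, 72.9% at 0.5, 82.0% at 1 and 98.0% at 2. It called 0.0792% of unchanged genes, or 9 genes. Only 48, 48, 50 and 50 genes were changed at these sizes, a far smaller share than was called in the data. These rates therefore need not hold for the data. In the same comparison, simulated with the cholesterol synthesis list lowered by 0.4, that list was called and no other. The simulated genes were drawn independently, so this cannot show false list calls that arise when genes of a list vary together.

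The alternatives set beforehand were scaling by DESeq2 size factors, by library size alone or by upper quartile; no filter, or at least 1 CPM in 3 libraries; DESeq2 1.42.0, limma-voom and robust edgeR; the replicate number as a block; leaving out each library in turn; an adjusted p under 0.01, and a change of at least 2-fold; and camera with an estimated correlation and fry for lists. Chosen after seeing the data were a correction for GC content and transcript length, a test of genes with at least 95% unique 31-base words, and a test without the 20 most abundant genes. Tables were joined and plotted with Python 3.11.15, pandas and matplotlib.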

Results

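Gene expression was measured by messenger RNA sequencing in peritoneal macrophages from mice that carried ID8 tumours, a mouse ovarian cancer model, and that had received chemotherapy 1 week earlier. The cells were obtained by washing the peritoneal cavity and keeping what adhered to plastic. The mice were fed a control diet (3 libraries) or a high fat diet (3 libraries). Total estimated counts per library were 28740724, 28808061 and 28109108 on control diet. On high fat diet they were 30486182, 31761487 and 31032637. The table holds 14108 genes. By its labels, the comparison addresses how a high fat diet changes the state of these macrophages after chemotherapy. The origin of the cells is taken up below and stays open. Below, CPM is the count of a gene per 1e6 counts of its library, with the library total adjusted by trimmed mean of M values scaling, group values are means ± SD with n = 3 libraries per diet, and log2 fold changes are high fat over control diet ± SE. Coordinates are those of the mm10 build.

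On high fat diet most measured interferon-stimulated and inflammatory transcripts of the macrophage libraries fell. Transcripts of macrophage receptors went both ways, with Csf1r and Tlr7 among the rises and the scavenger receptor Msr1 among the falls. Irf7, a transcription factor that drives type I interferon genes (ENSMUSG00000025498, chromosome 7, 141262706 to 141266481), fell from 273 ± 7.48 to 3.11 ± 0.305 CPM, a log2 change of -6.45 ± 0.07 (edgeR adjusted p = 1.6e-10). Ccl5, a chemokine that attracts T cells (ENSMUSG00000035042, chromosome 11, 83525778 to 83530518), fell from 173 ± 2.38 to 0.923 ± 0.0832 CPM (log2 change -7.55 ± 0.07, edgeR adjusted p = 6.9e-11). Csf1r, the receptor for the macrophage growth factor CSF-1 (ENSMUSG00000024621, chromosome 18, 61100598 to 61132149), rose from 97.1 ± 1.40 to 733 ± 17.4 CPM, or 7.56-fold (log2 change 2.92 ± 0.04, edgeR adjusted p = 4.3e-10). Tlr7, an endosomal sensor of single-stranded RNA, rose from 17.2 ± 0.939 to 168 ± 15.5 CPM (9.74-fold, edgeR adjusted p = 7.9e-09).

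Of 11670 genes tested, 4007 were higher and 3960 lower on high fat diet at an adjusted p under 0.05, which is 68.3% of the genes tested. Of these, 1031 of the higher and 878 of the lower genes changed at least 2-fold, and 50 and 133 changed at least 8-fold. The 3 libraries of one diet lay entirely above the 3 of the other in 8436 genes (72.3%), where chance gives 10%. Libraries of the same diet had Spearman correlations across genes of 0.994 to 0.997, against 0.945 to 0.948 between diets, and the first principal component, with 77.3% of the variance, separated the diets. The common biological coefficient of variation was 8.18%. Nothing in the labels says that libraries of a diet came from separate mice, so the p-values measure the spread between these samples, which may be technical. The labels name no batch, so any unrecorded difference in handling between the diets cannot be told apart from diet.

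**Figure D1:**
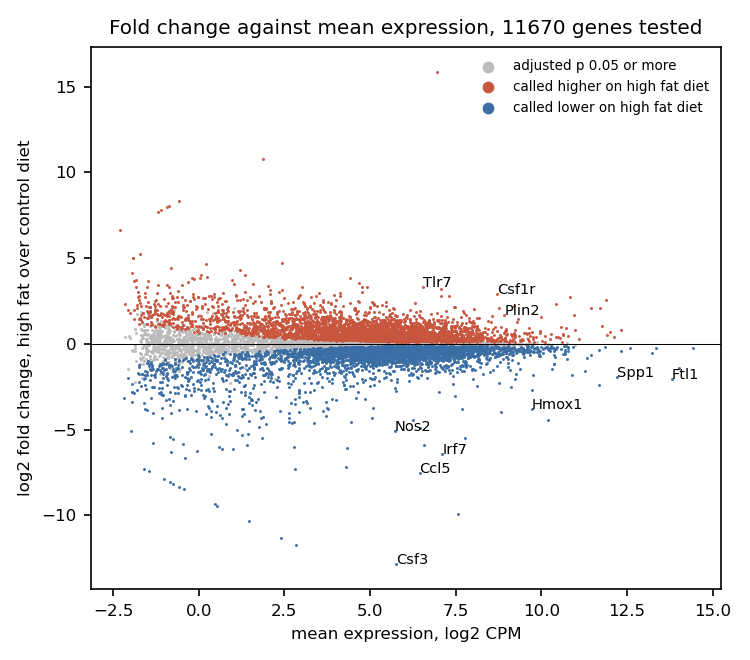
Log2 fold change (high fat over control diet, vertical axis) against mean expression (log2 CPM, horizontal axis) for the 11670 genes tested, one point per gene, with genes called higher in red, genes called lower in blue and the rest in grey. The 133 genes lower by at least 8-fold outnumber the 50 higher by as much; fitted values of genes with no counts on one diet, at the top and bottom, depend on the small count added in the fit.

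Besides Tlr7, the 12 largest rises included Igsf6, an immunoglobulin-superfamily protein of myeloid cells (from 2.74 ± 0.116 to 39.6 ± 1.19 CPM, 14.4-fold), Spn, the sialoglycoprotein CD43 (from 5.02 ± 0.492 to 49.7 ± 2.44 CPM, 9.90-fold) and Tra2a, a splicing regulator (from 4.11 ± 2.00 to 47.2 ± 5.95 CPM, 11.5-fold). Fgd2 (9.95-fold), Afap1l1, Cd300lg, Cbr2, Ceacam19 and Ankrd34a rose from under 2 CPM. Cars2 rose 26.5-fold, but its control counts were 32, 0 and 0, so the fold rests on 1 control library (log2 change 4.73, or 11.29 without control diet replicate 1), and its adjusted p was 0.055 with DESeq2. Maz, a zinc finger transcription factor, had no counts in the control libraries and 703 counts over the high fat libraries, at least 215-fold more, taking 3 counts over the group as the floor of a zero count. The 12 largest falls were led by Csf3, the granulocyte colony-stimulating factor G-CSF (ENSMUSG00000038067, chromosome 11, 98701263 to 98703629), with 3145, 2972 and 2883 counts in the control libraries and 0, 0 and 1 in the high fat libraries. That is a ratio of 9801 per library size, with a 95% counting interval of 1759 to 387157. Lif, a cytokine of the interleukin-6 family, fell from 13.6 ± 0.635 to 0.208 ± 0.0385 CPM (64.4-fold). Plk2, a stress-induced kinase, fell from 187 ± 5.50 to 3.10 ± 0.379 CPM (60.2-fold). Ptpn14 fell 148-fold, Efcab6 159-fold, Rgs16 70.7-fold and Apol9a 59.7-fold. Urah and Antxr1 had no counts on high fat diet and were at least 426-fold and 166-fold lower. Each of the genes in this paragraph had an edgeR adjusted p under 0.05, and the weakest was that of Cars2 (4.9e-04).

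The interferon response list had 33 tested genes, of which 31 fell, 1 rose (Ifi47) and 1 did not pass the test (Irf1), with a median log2 change of -2.72 (camera adjusted p = 1.9e-10). It was the only one of 31 lists tested that was also called with an estimated correlation (adjusted p = 0.0429). Rsad2, the antiviral protein viperin, fell from 39.3 ± 2.96 to 0.570 ± 0.114 CPM (68.4-fold). Oasl1 fell from 91.7 ± 3.50 to 15.3 ± 0.845 CPM (6.01-fold) and Oas3, which is activated by double-stranded RNA, from 154 ± 2.51 to 51.8 ± 0.824 CPM (2.96-fold). In the inflammatory cytokine and NF-kB target list 22 of 28 genes fell and 4 rose (Icam1, Nlrp3, Nfkb1 and Relb; median -2.41, camera adjusted p = 2.3e-06), and the call was lost with an estimated correlation (adjusted p = 0.0666). The neutrophil-attracting chemokine Cxcl2 fell from 427 ± 12.4 to 9.66 ± 0.957 CPM (44.2-fold) and Ccl3 from 2223 ± 155 to 101 ± 8.39 CPM (22.03-fold). Nos2, the inducible nitric oxide synthase, fell from 102 ± 7.80 to 3.05 ± 0.311 CPM (33.4-fold, edgeR adjusted p = 1.6e-09). Il1b was low on both diets, at 0.747 ± 0.216 and 0.0408 ± 0.0707 CPM (log2 change -4.04, or -7.46 without high fat diet replicate 2; edgeR adjusted p = 0.0016). The MHC class I presentation list had 16 of 22 genes lower and 5 higher (median -0.73, camera adjusted p = 0.0021, adjusted p = 0.460 with an estimated correlation). In it the peptide transporter Tap1 fell from 131 ± 3.13 to 49.9 ± 2.12 CPM (2.62-fold) and the chaperone Calr from 1849 ± 59.2 to 678 ± 33.9 CPM (2.73-fold). H2-Q6 and H2-Q7 also fell, but share much of their sequence with other class I genes and are uncertain. On the same diet 2 of the 3 lists fixed as signs of RNA quality moved beside these and the later lists. Mitochondrially encoded mRNAs rose in 12 of 13 cases (camera adjusted p = 5.0e-05, adjusted p = 0.460 with an estimated correlation) and cytosolic ribosomal protein genes fell in 60 of 74 (camera adjusted p = 1.1e-07, adjusted p = 0.507 with an estimated correlation).

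**Figure D2:**
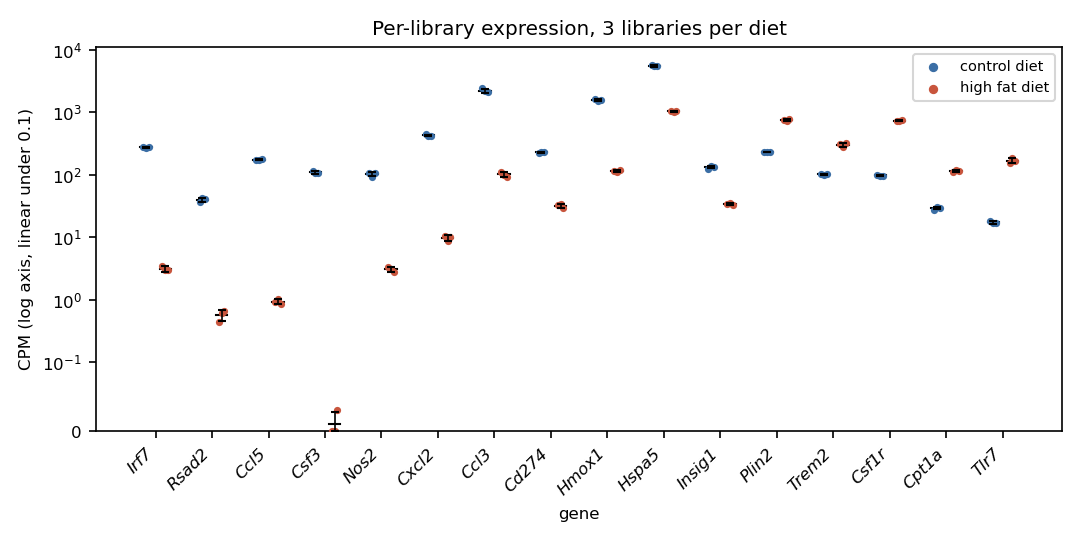
CPM in each library (points, vertical log axis that is linear under 0.1) for 16 genes, with the mean (bar) and SD (whiskers, stopped at 0) of 3 control diet libraries (blue) and 3 high fat diet libraries (red). Every control library lies above every high fat library from Irf7 to Insig1, and every high fat library above every control library from Plin2 to Tlr7.

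Genes of oxidative stress defence and protein folding were mostly lower on high fat diet. Of 24 tested NRF2 and oxidative stress genes 16 fell and 6 rose (median -0.83, camera adjusted p = 0.0036, adjusted p = 0.407 with an estimated correlation). Hmox1, the heme-degrading oxygenase (ENSMUSG00000005413, chromosome 8, 75093621 to 75100589), fell from 1573 ± 38.1 to 114 ± 3.10 CPM (13.8-fold, edgeR adjusted p = 1.6e-10). Gclm, a subunit of the glutathione-synthesis enzyme, fell from 285 ± 5.50 to 56.8 ± 3.39 CPM (5.01-fold) and the autophagy adaptor Sqstm1 from 3711 ± 61.4 to 1254 ± 39.7 CPM (2.96-fold). The iron-storage ferritin genes Fth1, added after its values were seen, and Ftl1 together took 4.58 ± 0.105% of counts on control diet and 1.49 ± 0.0682% on high fat diet. Only 35.9% of the sequence of Ftl1 is unique among annotated transcripts, so its share is uncertain. Of 25 unfolded protein response genes 19 fell and 6 rose (median -0.48, camera adjusted p = 0.0038, adjusted p = 0.460 with an estimated correlation). The endoplasmic reticulum chaperone Hspa5 fell from 5513 ± 119.7 to 1028 ± 29.1 CPM (5.36-fold, edgeR adjusted p = 6.0e-10). Hyou1 fell from 976 ± 36.03 to 346 ± 12.4 CPM and Manf from 401 ± 11.5 to 136 ± 5.72 CPM. In the p53 and DNA damage list 16 of 25 genes fell and 5 rose (18 and 5 adjusted over the list alone; median -0.46, camera adjusted p = 0.0096, adjusted p = 0.297 with an estimated correlation). Gadd45b, which NF-kB also induces, fell from 146 ± 4.29 to 6.79 ± 0.727 CPM and the cell cycle inhibitor Cdkn1a from 113 ± 2.50 to 52.3 ± 2.53 CPM. The antiproliferative gene Btg2 rose from 4.82 ± 0.343 to 16.3 ± 0.496 CPM. Of 24 immediate early genes 11 fell and 7 rose, without a call (camera adjusted p = 0.330).

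Lipid genes did not move one way. Plin2, the coat protein of lipid droplets (ENSMUSG00000028494, chromosome 4, 86648386 to 86670060), rose from 228 ± 1.26 to 742 ± 23.8 CPM (3.25-fold, edgeR adjusted p = 7.9e-09). The fatty acid carriers Fabp4 and Fabp5 fell from 23.96 ± 1.41 to 5.73 ± 0.302 CPM and from 809 ± 34.7 to 278 ± 15.4 CPM. The scavenger receptor Msr1 fell from 141 ± 7.08 to 39.6 ± 2.65 CPM. The fatty acid transporter Cd36 stayed under 1 CPM on both diets (0.820 ± 0.0439 and 0.136 ± 0.119 CPM, edgeR adjusted p = 0.0056). In all, 5 of 16 lipid uptake and storage genes rose and 7 fell, without a call (camera adjusted p = 0.568). Fatty acid oxidation was called higher, with 12 of 20 genes up and 3 down (median 0.35, camera adjusted p = 0.0359, adjusted p = 0.460 with an estimated correlation). In that list Cpt1a, which admits long-chain fatty acids to mitochondria, rose from 29.1 ± 1.40 to 114 ± 4.50 CPM (3.92-fold). Cholesterol synthesis was called lower, with 17 of 22 genes down and 3 up (median -0.41, camera adjusted p = 0.0062, adjusted p = 0.460 with an estimated correlation). Its falls included Insig1 (from 132 ± 6.59 to 34.3 ± 1.24 CPM). Neither fatty acid synthesis (3 of 12 up, 4 down, camera adjusted p = 0.760) nor cholesterol efflux and LXR targets (6 of 13 up, 2 down, camera adjusted p = 0.209) was called. In the former the desaturase Fads1 rose from 122 ± 3.33 to 216 ± 3.70 CPM and Scd1 fell from 57.6 ± 1.19 to 28.6 ± 2.87 CPM. In the latter the phospholipid transfer protein Pltp rose from 71.9 ± 1.03 to 149 ± 3.98 CPM and Apoe fell from 10.96 ± 0.631 to 3.62 ± 0.750 CPM. The lipid-associated macrophage list split, with 5 of 20 genes up and 12 down (camera adjusted p = 0.181). In it the lipid receptor Trem2 rose from 101 ± 1.29 to 303 ± 23.97 CPM (2.99-fold, edgeR adjusted p = 8.8e-08). Spp1, or osteopontin, fell from 7479.8 ± 418 to 1978 ± 81.1 CPM (3.78-fold, edgeR adjusted p = 1.0e-08).

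**Figure D3:**
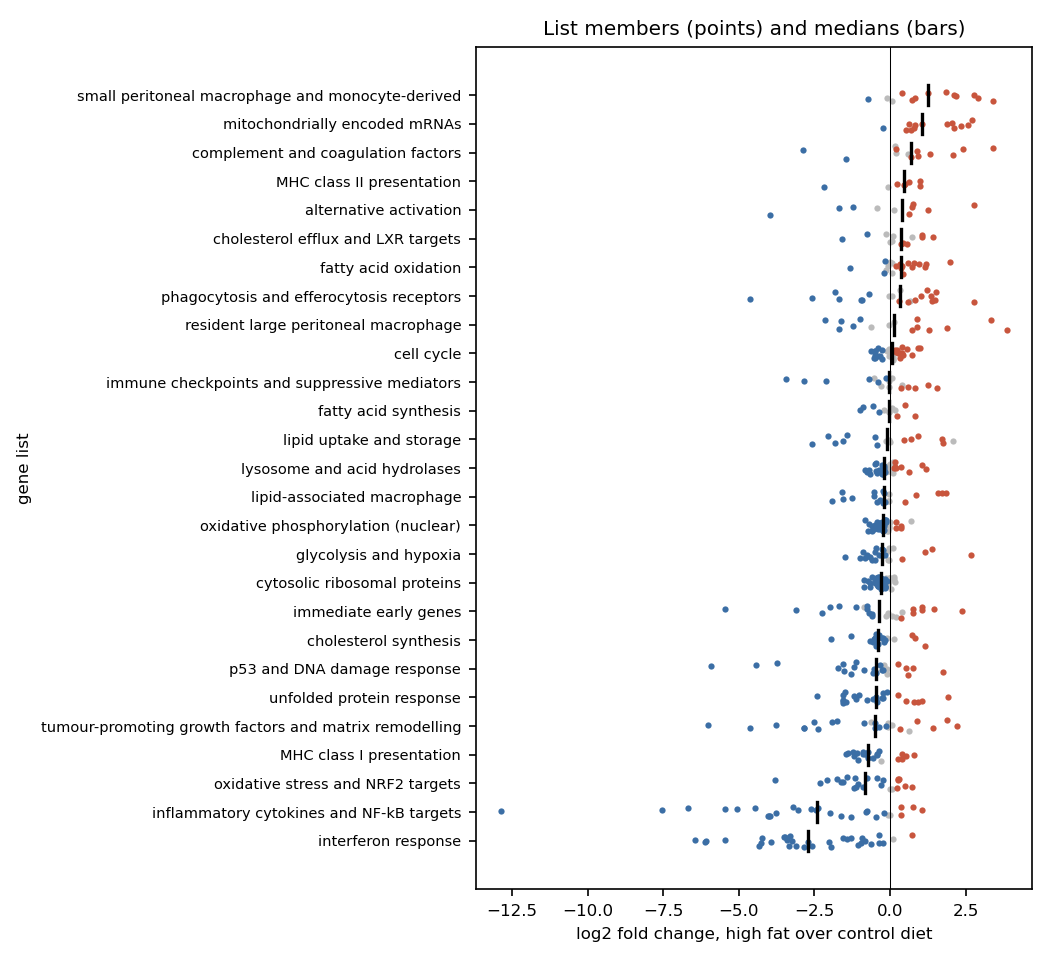
Log2 fold change (high fat over control diet, horizontal axis) of each tested member of the 27 lists on macrophage biology and RNA quality (vertical axis), with called members in red (higher) or blue (lower), others in grey, and the list median as a black bar. Medians run from -2.72 for the interferon response to 1.27 for small peritoneal and monocyte-derived macrophage genes.

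Genes of small peritoneal and monocyte-derived macrophages rose as a list, with 10 of 13 up and 1 down (median 1.27, camera adjusted p = 0.0036, adjusted p = 0.294 with an estimated correlation). This is bulk RNA with 13 of the 27 fixed members tested, so the rise names no cell type. Besides Csf1r, the integrin Itgax rose from 5.13 ± 0.316 to 18.3 ± 0.931 CPM and the chemokine receptor Ccr2 from 0.929 ± 0.334 to 4.00 ± 0.695 CPM (edgeR adjusted p = 1.7e-04). The interferon-induced Ifitm3 fell from 326 ± 2.99 to 195 ± 11.5 CPM. Complement and coagulation genes were called higher, with 8 of 13 up and 2 down (median 0.69, camera adjusted p = 0.0379, adjusted p = 0.407 with an estimated correlation). C3, the central complement component, rose from 9.16 ± 0.955 to 38.4 ± 1.79 CPM and its receptor C3ar1 from 40.8 ± 1.51 to 65.8 ± 1.76 CPM. This list lost its call without high fat diet replicate 3 (adjusted p = 0.0534), with scaling by library size alone (0.0802) and with a filter of 1 CPM (0.0616). Resident large peritoneal macrophage genes were not called (7 of 15 up and 5 down, or 7 and 6 adjusted over the list alone; camera adjusted p = 0.803). Laptm5 rose from 553 ± 12.8 to 1037 ± 39.5 CPM, Adgre1, which encodes F4/80, rose from 13.5 ± 0.415 to 22.4 ± 3.48 CPM, and Bhlhe40 fell from 228 ± 3.22 to 97.9 ± 3.46 CPM. Gata6 and Timd4 were not analysed here. The alternative activation list was not called either (5 of 10 up, 3 down, camera adjusted p = 0.602), and its mean log2 change (-0.10) and median (0.39) differ in sign. The mannose receptor Mrc1 rose from 0.530 ± 0.159 to 3.70 ± 0.412 CPM and the transglutaminase Tgm2 fell from 33.5 ± 0.996 to 14.2 ± 0.342 CPM. Arg1 was near 0 on both diets (0.169 ± 0.116 and 0.0627 ± 0.0836 CPM) and was not tested. In the MHC class II list 6 of 8 genes rose and 1 fell, without a call (camera adjusted p = 0.191). The protease Ctss rose from 1450.4 ± 48.04 to 2025 ± 50.5 CPM and the costimulatory receptor Cd40 fell from 22.8 ± 2.32 to 5.07 ± 0.841 CPM. H2-Aa itself was at 0.0719 ± 0.0613 and 0.104 ± 0.0798 CPM, below the filter.

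Among growth factors and matrix remodelling genes 14 of 24 fell and 5 rose (15 and 6 adjusted over the list alone; median -0.50, camera adjusted p = 0.0099, adjusted p = 0.407 with an estimated correlation). Among the falls were the urokinase Plau (from 941 ± 34.3 to 166 ± 2.07 CPM, 5.65-fold) and the gelatinase Mmp9 (from 24.8 ± 1.09 to 1.81 ± 0.286 CPM, 13.6-fold). Cd274, which encodes the checkpoint ligand PD-L1 (ENSMUSG00000016496, chromosome 19, 29367455 to 29388095), fell from 227 ± 5.68 to 31.8 ± 2.27 CPM (7.15-fold, edgeR adjusted p = 4.1e-09). Of the 17 tested checkpoint and suppressive mediator genes 6 fell and 5 rose, without a call (camera adjusted p = 0.557). Lgals9 fell from 46.5 ± 1.90 to 10.7 ± 0.412 CPM and Ptges from 16.4 ± 0.777 to 1.53 ± 0.380 CPM, and the phagocytosis-checkpoint receptor Sirpa rose from 363 ± 12.7 to 875 ± 11.5 CPM. Phagocytosis receptors went both ways (10 of 21 up and 7 down, or 11 and 7 adjusted over the list alone; camera adjusted p = 0.286). The inhibitory Fc receptor Fcgr2b rose from 30.3 ± 0.174 to 79.4 ± 3.14 CPM and the integrin Itgb3 fell from 12.6 ± 0.995 to 0.509 ± 0.0743 CPM. Lysosomal genes also went both ways (8 of 35 up, 18 down, camera adjusted p = 0.142); among the rises was the mannosidase Man2b1 (from 71.9 ± 4.02 to 162 ± 3.93 CPM).

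Most mitochondrially encoded transcripts rose, while most nuclear-encoded respiratory chain and ribosomal protein transcripts fell. The mitochondrial genes took 3.99 ± 0.213% of counts on control diet and 6.39 ± 0.360% on high fat diet. Of these genes 12 of 13 rose and 1 fell (median 1.05, camera adjusted p = 5.0e-05, adjusted p = 0.460 with an estimated correlation). The rises included mt-Nd1 (from 483 ± 34.4 to 3141 ± 137 CPM) and mt-Cytb (from 1087 ± 59.8 to 6509 ± 518 CPM). Nuclear copies of mitochondrial sequence, chosen after their values were seen, moved too: Gm10925 went from no counts to 24049 counts over the high fat libraries and Gm29216 fell from 382 ± 42.95 to 0.398 ± 0.346 CPM. Since 0% and 2.81% of their 31-base words are unique, the split between these copies and the mitochondrial genes is uncertain. Of 43 nuclear oxidative phosphorylation genes 29 fell and 4 rose (median -0.24, camera adjusted p = 4.9e-04, adjusted p = 0.566 with an estimated correlation). Sdhd, a subunit of succinate dehydrogenase, fell from 324 ± 8.31 to 199 ± 2.85 CPM. Cytosolic ribosomal protein genes fell in 60 of 74 cases and rose in none (1 adjusted over the list alone; median -0.29, camera adjusted p = 1.1e-07, adjusted p = 0.507 with an estimated correlation). Rpl9 fell from 1002 ± 16.02 to 640.1 ± 25.7 CPM. Glycolysis and hypoxia genes were lower in 16 of 26 cases and higher in 4 (median -0.27, camera adjusted p = 0.0303, adjusted p = 0.460 with an estimated correlation). Pfkfb3, an activator of glycolysis, fell from 55.3 ± 2.28 to 19.5 ± 1.54 CPM, but the mitochondrial gatekeeper kinase Pdk1 rose from 32.2 ± 1.31 to 84.7 ± 1.85 CPM. The cell cycle list was high in every library, with a median of 106 CPM, and was not called between diets (14 of 36 up, 11 down, camera adjusted p = 0.568). In it Ccnb2 rose from 41.2 ± 2.43 to 78.2 ± 3.08 CPM and Pcna fell from 639 ± 18.9 to 441 ± 6.82 CPM.

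Most markers of other cells of the peritoneal cavity were low on both diets. Of 212 marker genes fixed for 11 cell types 88 were in the count table and 16 exceeded 10 CPM on average, several of which macrophages also express, such as Bst2 (248 ± 11.4 and 75.98 ± 4.68 CPM) and Xbp1 (121 ± 5.22 and 172 ± 6.08 CPM). The T cell marker Il7r fell from 74.8 ± 4.25 to 42.8 ± 1.27 CPM, and the endothelial marker Vwf rose from 47.3 ± 2.66 to 65.2 ± 4.99 CPM. The dendritic cell markers Wdfy4 and Irf8 rose from 101 ± 6.97 to 170.2 ± 21.1 CPM and from 44.96 ± 0.683 to 61.03 ± 1.81 CPM, and the B cell marker Cd37 from 65.04 ± 3.07 to 85.1 ± 6.57 CPM. No list of another cell type was called: dendritic cell markers (4 of 9 up, 3 down, camera adjusted p = 0.811), B and plasma cell markers (3 of 5 up, none down, 0.209), T cell markers (2 of 5 up, 2 down, 0.9996) and endothelial markers (2 of 5 up, 1 down, 0.811). For T cell markers the median was 0.69 though camera ranked the list lower, and for endothelial markers the mean was -0.20 and the median 0.15. The other 7 lists had fewer than 5 tested genes and no list test. Among them, fibroblast markers had 3 of 4 up (4 adjusted over the list alone), led by Pi16 (from 6.62 ± 0.117 to 30.3 ± 1.37 CPM), and adipocyte markers 1 of 3 up and 2 down. In the NK cell list 1 of 2 was up, Il1rl1 (from 3.93 ± 0.602 to 13.05 ± 1.25 CPM), and 1 down. Among neutrophil markers 1 of 4 was up, Csf3r (from 3.28 ± 0.145 to 17.1 ± 0.680 CPM), and 1 down, Mmp9. For mast cells, eosinophils and basophils the 1 tested gene, Hdc, fell from 1.32 ± 0.323 to 0.291 ± 0.0990 CPM. Erythroid and platelet markers had 1 of 3 up and 1 down. Neither of the 2 tested genes of tumour epithelium and mesothelium was called; the highest of that list, Igfbp6, was at 1.79 ± 0.285 and 2.48 ± 0.261 CPM.

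The pan-leukocyte gene Ptprc, or CD45, was at 285 ± 8.87 CPM on control and 371 ± 34.8 CPM on high fat diet (edgeR adjusted p = 8.0e-04). Several transcripts, chosen after their values were seen, describe the cells of all 6 libraries. The Y-linked genes Ddx3y, Kdm5d, Uty and Eif2s3y were expressed in every library, Eif2s3y at 102 ± 4.92 and 91.5 ± 6.22 CPM and Uty, the lowest, at 38.9 ± 1.32 and 27.97 ± 3.44 CPM. Pycard, which encodes the inflammasome adaptor ASC, lay between 0.0612 and 0.178 CPM in the 6 libraries. The proliferation marker Mki67 was at 519.8 ± 17.02 and 681 ± 24.6 CPM and Top2a at 514 ± 8.67 and 550.3 ± 25.4 CPM. Cd5l, a product of tissue macrophages, was at 0.194 ± 0.106 and 0.176 ± 0.0482 CPM.

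**Figure D4:**
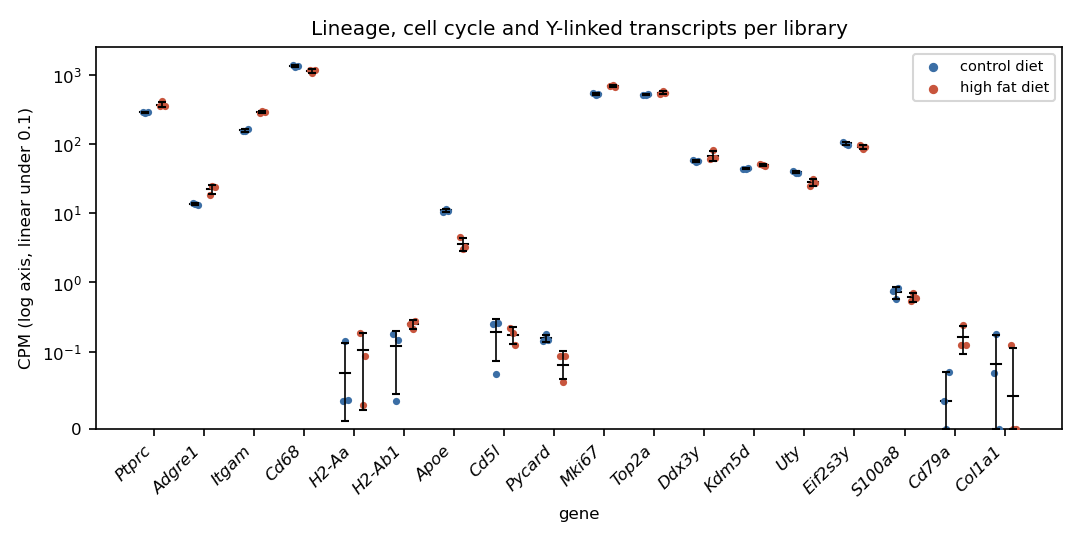
CPM in each library (points, vertical log axis that is linear under 0.1) for 18 genes of leukocyte and macrophage identity, antigen presentation, proliferation, the Y chromosome and other cell types, with the mean (bar) and SD (whiskers, stopped at 0) of 3 libraries per diet. The Y-linked and proliferation genes lie above 10 CPM in all 6 libraries, and Pycard, H2-Aa, H2-Ab1 and Cd5l under 1 CPM.

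The authors' deposited table of their own comparison lists 5911 genes, 3086 higher and 2825 lower on high fat diet, with absolute log2 changes from 0.263 (1.2-fold) and p-values up to 0.00995. Of the 5826 of these genes that were tested with edgeR, 5713 were called in the same direction, 102 were not called and 11 were called in the opposite direction. Those 11 include Gnaq, named because of its values: in the authors' deposited table its log2 change is -0.43, against 1.01 from the counts.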

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

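The correction for GC content and transcript length, the test of uniquely mappable genes and the test without the 20 most abundant genes were chosen after seeing the data. Under the other scalings and filters, DESeq2, limma-voom and robust edgeR, 3843 to 4748 genes were called higher and 3258 to 3994 lower, against 4007 and 3960, and none of the main calls changed direction. With scaling by library size alone 4748 were higher and 3258 lower, so the even balance of the main test depends on the scaling. Leaving out each library in turn gave 3681 to 4040 higher and 3566 to 4052 lower. An adjusted p under 0.01 left 3319 and 3260. Requiring a change of at least 2-fold at an adjusted p under 0.05 left 1031 and 878, by construction. Of genes with at least 95% unique 31-base words, 2612 were higher and 2507 lower, since only 7425 genes were tested. The correction for GC content and length gave 4114 and 4071, with 1 call in the opposite direction, and leaving out the most abundant genes 4035 and 3898.

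Camera called 4 lists higher and 11 lower. With an estimated correlation, which also limits the test to the 4 residual degrees of freedom of the libraries, it called 0 and 1 (1 and 3 at an unadjusted p under 0.05), and 14 lists lost their call. Fry called 10 and 17, since it does not compare a list with other genes. Of the 159 named genes tested, 10 crossed the threshold under at least 1 alternative. In 2535 recomputed values none was called in the opposite direction. Genes that were not called may have changed sign. Same-numbered libraries of the diets did not deviate together (correlations across genes 0.07, -0.04 and 0.01), and not every library correlated best with its own number. No pairing by number was seen, though the labels do not say whether there is one. With the replicate block 3904 genes were higher and 3857 lower. At 28109108 to 31761487 counts per library, genes under about 0.1 CPM cannot be told from zero.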

Other observations

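The tests of cell origin and of the interferon pattern were chosen only after the result was seen; the tests against the authors' table, of gene families and of isoforms were set before their results were computed. Apart from Tlr7, the genes in this paragraph were picked after their values were seen. Of 8 tested Toll-like receptor genes 6 were higher and none lower on high fat diet, and Tlr1 and Tlr3 did not pass (edgeR adjusted p = 0.666 and 0.210). Besides Tlr7, Tlr13, an endosomal sensor of ribosomal RNA, rose from 18.9 ± 1.4 to 75.3 ± 2.07 CPM (3.97-fold), Tlr2, a sensor of bacterial lipoproteins, from 80.4 ± 1.06 to 210.2 ± 6.35 CPM (2.62-fold) and Tlr4, the endotoxin receptor, from 56.1 ± 1.93 to 121 ± 12.7 CPM (2.16-fold, edgeR adjusted p = 2.1e-06). The endotoxin co-receptor Cd14 rose from 254 ± 5.57 to 401 ± 24.3 CPM and Cybb, a subunit of the phagocyte NADPH oxidase, from 71.8 ± 1.16 to 185 ± 23.6 CPM. In the other direction, Acod1, the itaconate-producing enzyme that inflammatory stimuli induce, fell from 171 ± 6.44 to 5.69 ± 0.686 CPM (30.1-fold), Il1rn, the interleukin-1 receptor antagonist, from 382 ± 8.93 to 27.3 ± 1.05 CPM (13.99-fold) and the growth regulator Myc from 41.9 ± 1.93 to 1.80 ± 0.126 CPM (23.3-fold). The tumour necrosis factor gene Tnf fell from 467 ± 6.34 to 86.2 ± 11.4 CPM (5.41-fold, edgeR adjusted p = 5.0e-08).

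In a scan of 129 families of at least 10 tested genes that share a symbol stem, 3 passed camera with the preset correlation, and none of them with an estimated one (adjusted p = 0.959 for each). They were Rpl (lower, adjusted p = 9.1e-04 with the preset correlation), Ifi (lower, adjusted p = 0.0073) and the splicing regulators Srsf (higher, adjusted p = 0.011). With an estimated correlation 0 families passed camera (5 had an unadjusted p under 0.05), so whole families shifted beyond the fixed lists are not shown. Gene by gene, 9 of the 10 Srsf genes were higher and 1, Srsf11, lower, with a median log2 change of 1.24. Srsf6 rose from 63.2 ± 2.26 to 284 ± 14.0 CPM and Srsf1 from 146 ± 8.98 to 408 ± 8.50 CPM, a log2 change of 1.48 against 0.49 in the authors' deposited table. Of genes also picked after their values were seen, Mat2a, which makes the methyl donor S-adenosylmethionine and whose transcript is regulated by intron retention, rose from 26.4 ± 1.01 to 240.4 ± 13.3 CPM (9.10-fold), while the SR protein kinases Clk1 and Clk4 were lower (from 122 ± 5.68 to 96.96 ± 13.6 CPM and from 58.2 ± 1.39 to 42.00 ± 3.87 CPM). A hypothesis is that the rise of the Srsf genes may include a change of isoforms. The gap between the fold change in the authors' deposited table and that from the counts was over 0.2 in 3 of the 8 Srsf genes in both (Srsf1, Srsf5 and Srsf2, at 1.02, 0.628 and 0.271). Its median over the 8 was 0.0627, at percentile 82.0 of 10000 random sets of genes with several transcripts, short of the 95th that was set beforehand and above the 50th that would have counted against it; transcript-level counts would be needed.

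The cell profile of the 6 libraries deserves a closer look. All expressed Y-linked genes (at least 24.6 CPM) and cell cycle genes at high levels, while Pycard was at most 0.178 CPM, H2-Aa and Cd5l were under 1 CPM, and 5 of 20 resident peritoneal macrophage genes in the table (25.0%) exceeded 10 CPM, with a list median of 0.837 CPM; the other 8 fixed genes of that list were not analysed here. The ID8 line comes from a female mouse, the labels do not give the sex of the mice, and a widely used cultured macrophage line is male and known to lack ASC. Cells of a cultured male macrophage line are a candidate explanation that stays open and was not tested independently, since the Pycard and Y-linked values are those that raised it; they do not exclude it. The list median of 0.837 CPM goes against dividing peritoneal macrophages of male mice, which stay open, since the share of 25.0% lies between the bounds for and against them, of which the lower was set after the share was known, and no lavage library of known origin was used here. For tumour cells as the source of the cell cycle transcripts, 5 of 25 tumour or mesothelial markers were in the table. Their highest mean over the 6 libraries was 2.13 CPM, beside a cell cycle median of 106 CPM, which cannot decide the question. Tumour cells stay open too, since the other 20 markers were not analysed here and no ID8 library was used here for the level of the 5.

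The fall of interferon and inflammatory genes was set against technical trends, RNA quality and diet. A trend with GC content or transcript length does not account for it: after its removal the interferon median was -2.72, with 31 of 33 genes lower, and the trend explained 0.231% of the variance of fold changes. Neither does the scaling: with library size alone the interferon median was -2.63. That change moves all genes nearly alike, and the median over all tested genes went from 0.00158 to 0.0964. It does not test the effect of a few abundant genes. Without the 20 most abundant genes 7895 main calls were kept in the same direction and 0 were reversed, but the interferon median of that setting is not given here. A difference in RNA quality stays open: the mitochondrial share of counts was 1.603 times as high on high fat diet, and most ribosomal protein genes were lower. Within the diets the mitochondrial share had a correlation of 0.329 with the interferon list over only 6 libraries. Diet stays open as the biological explanation, beside unrecorded differences in handling between the diets, as a hypothesis. Diet could account for the fall only if the cells came from the mice, and a cultured male macrophage line stays open too.

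Fold changes in the authors' deposited table differ from those of DESeq2 on the counts for part of the genes. Gaps over 0.2 on the log2 scale, after a median of 0.03 was taken off, occurred in 0.170% of 589 genes with 1 annotated transcript and in 12.4% of 5303 genes with several. Low counts do not account for this, since 9.63% of the 3851 genes with several transcripts and a mean count of 500 or more had such gaps. Transcript length terms in the authors' fit, which adjust a gene's counts when its isoforms shift, are consistent with the difference by transcript number, and could turn the direction of genes such as Gnaq.

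Of the 10 ways to split the 6 libraries into groups of 3, the real one called 7967 genes and the highest of the others 0; it called 15 lists, and the highest of the others 12. In each case 1 split, the real one, gave as many, and 10 splits are too few for a share under 0.05. Every other split put both diets in each group, so the diet difference widened the spread within groups and left little room for gene calls. Camera with the preset correlation still called up to 12 lists between such mixed groups. Each mixed group held more libraries of one diet than of the other, so part of the diet difference remained between them. These list counts are therefore no measure of calls made without a diet difference.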
